A study of Mus musculus with 16 samples.

How the data were processed

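RNA from the small intestine of 16 mice was measured on Illumina bead arrays with 25697 probes. Per the labels' protocols, mice with loxP-flanked Hnf4a alleles, with or without the tamoxifen-inducible Cre recombinase driven by the villin promoter, received 1 mg tamoxifen by gavage on each of 5 days. After 3 weeks they were given 14 Gy of whole-body gamma irradiation, and tissue was taken 96 hours later. The 8 Cre-positive mice form the knockout group and the 8 Cre-negative mice the wildtype group. The protocol gives the wildtype mice as carrying the loxP-flanked alleles, while another label gives their genotype as Hnf4a+/+, and the labels do not settle which holds. All mice were irradiated, so the arrays hold no unirradiated reference, and Cre status goes with genotype. RNA was extracted with TRI Reagent, cleaned on RNeasy columns and amplified to biotin-labelled cRNA, per the labels' protocols.

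The deposited values are of 3 kinds. The intensity of each probe on each array is not normalized, per the file headers. The detection p-value beside each intensity, per the file headers, moves in steps that correspond to 798 negative control beads per array. The deposited series table holds an intensity per probe as well, with no method named: its columns keep the rank order of their own array exactly (rank correlation 1), their medians lie between 158.5 and 159.0, and sorted columns differ by at most 2.66% of their mean. Its scale is thus linear and quantile normalized with no sign of background subtraction, and it served only as an alternative. The scanner software and its settings are not given in the sources used here.

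Intensities were background corrected with the normexp model of limma 3.58.1 in R 4.3.3, with the negative control mean and SD inferred from the detection p-values and an offset of 16, then quantile normalized and converted to log2. The correction and the offset shrink the fold changes of dim probes. A probe was kept if its detection p was under 0.05 on at least 6 of the 16 arrays, which left 13460 probes. For genes with several probes the brightest was tested, which gave 10143 genes; disagreeing probes are named where they concern a gene given below. Symbols on the array are old. Of the probes, 20733 carried a current symbol of the RefSeq table for assembly GRCm38.p6, 3903 were updated through a unique synonym, and 1061 kept the array's own name.

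Knockout was compared with wildtype by limma's moderated test (lmFit and eBayes, genotype as the only term) with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p for a single gene is from this limma test, and every log2 difference is knockout minus wildtype with its standard error (SE). Gene lists, 37 in all, were fixed before the data were examined, and lists with fewer than 4 tested members were left untested. The 35 lists that remained were set against the other genes with limma's camera at a preset correlation of 0.01. The mean of the members on each array was compared by an exact two-sided permutation test over all 12870 splits of 8 against 8, whose smallest p is 0.000155. Both were adjusted over the 35 lists. Camera with an estimated correlation and limma's fry were run beside them. Of the genes in the lists, 20 stand in more than 1 list.

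Genes are named by a rule fixed before the data were examined: Hnf4a; the 12 largest increases and 12 largest decreases past the threshold with the same sign on both slides and a gene symbol; and from each list up to 4 past-threshold members with the largest change, or the member with the smallest p where none passed. Some genes that the rule picks are not reported here. A gene detected on at most 4 of 8 arrays of a group (the limit fixed beforehand was none, and was widened after seeing the data) is given as a lower bound, the bright group's mean set against the higher, per array, of the lowest detected signal and the probe's own.

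The arrays lie on 2 slides of 8, each with 4 wildtype and 4 knockout arrays. Slide as a block leaves every difference unchanged, because the groups are balanced. Between 46.9% and 53.1% of probes were detected per array (12060 to 13656 probes), and the number of arrays limits the precision. The design text calls the samples mice, so the replicates were taken as separate animals. Correlations between arrays lay between 0.908 and 0.989, so no array was counted as a duplicate. No deposited per-sample column was left unmapped.

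The procedure was tested on simulated intensities of this comparison with 10144 genes reaching the test. All 34 genes given a log2 change of -2 were recovered, 25 of 34 at -1 and 13 of 33 at -0.5. For increases, all 32 that reached the test were recovered at 2 (1 more failed the detection filter), 28 of 33 at 1 and 17 of 33 at 0.5. Of the calls, 5.95% fell on unchanged genes. A cell cycle list lowered by 0.4 was called, and no other list was. The simulated genes varied independently, so this says nothing about lists whose members vary together.

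Alternatives covered background correction, normalization, the detection filter, the rule for several probes, slide and replicate number as blocks, each slide alone, the variance model, array weights, each array left out, thresholds, marker means as covariates and other list tests. Figures were drawn with matplotlib 3.10.9.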

Results

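The series compares small intestine with and without intestinal epithelial HNF4A, a nuclear receptor transcription factor of the intestinal epithelium, 96 hours after 14 Gy of whole-body irradiation. It thus shows how tissue lacking the factor differs after damage. Tamoxifen was given before irradiation, and no unirradiated mice were measured. Whether a difference arose while the epithelium regrew or was already present before irradiation was therefore not tested. This holds for every gene and list below. There were 8 wildtype and 8 knockout mice with 1 array each. On average 49.7% ± 1.32 of probes were detected in wildtype and 50.8% ± 1.84 in knockout tissue (SD, n = 8 each; exact permutation p = 0.200, two-sided). The first principal component held 36.8% of the variance and parted the genotypes, with the lowest knockout array at 7.54 and the highest wildtype array at -10.7. The second held 13.7%. The Y-linked gene Ddx3y was detected on all 16 arrays, and Xist, expressed from the inactive X chromosome, on knockout array 8.

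Hnf4a itself was lower on every knockout array than on any wildtype array. Its single probe read 12.24 ± 0.16 log2 units in wildtype and 10.49 ± 0.19 in knockout tissue (SD, n = 8 each), a difference of -1.75 (SE 0.10, adjusted p = 2.06e-09, limma, with slide as a block 4.38e-09; exact permutation p = 0.000155, the smallest the splits can give). Knockout tissue thus held 29.8% of the wildtype signal. The highest knockout value was 10.71 and the lowest wildtype value 11.91. The difference was -1.80 on slide 1 and -1.70 on slide 2. Where the probe lies relative to the deleted exons is not given in the sources used here, and a probe outside them would not measure the deletion itself.

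**Figure D1:**
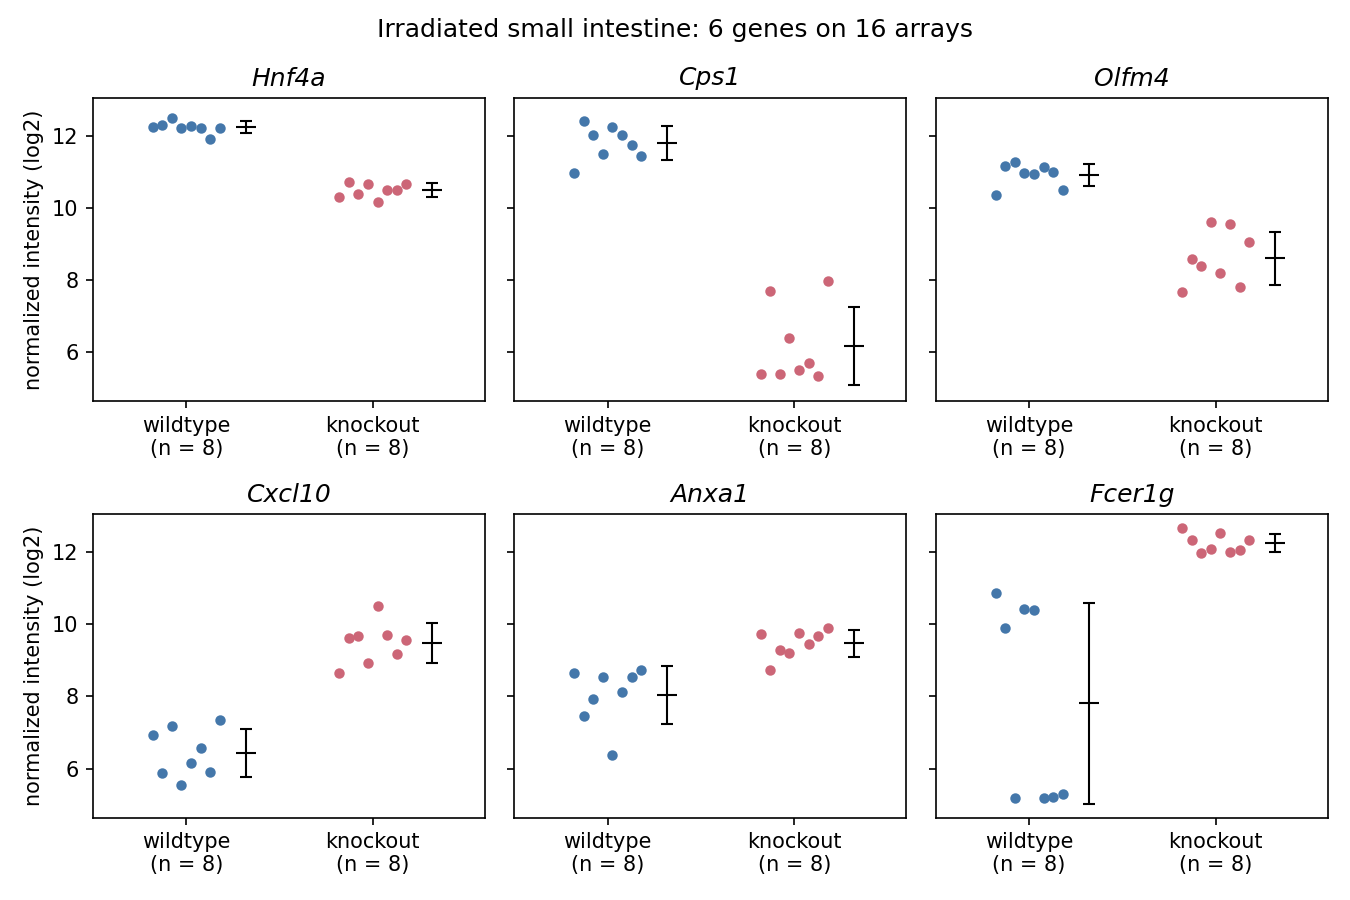
Normalized log2 intensity (vertical axis) of 6 genes on each of the 8 wildtype (blue) and 8 knockout (red) arrays; black bars give the group mean and SD. The groups do not overlap in any of the 6, and wildtype Fcer1g falls into 4 undetected arrays and 4 detected ones.

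Of 10143 genes tested, 3115 (30.7%) passed the threshold, 1374 higher and 1741 lower in knockout tissue. At an unadjusted p under 0.05 there were 4194, against 507 expected by chance. All 3115 had the same sign on both slides. The slides are balanced and the genes were chosen by their difference over both, so this is not independent replication. With slide as a block 3323 genes passed. Slide 1 alone, with 4 arrays per group, gave 758 genes, 737 of them among the 3115. Slide 2 alone gave 1335, 1237 of them among the 3115. At least 2-fold differences were fewer and lay more often on the side of increases, with 256 higher and 149 lower.

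The largest decreases included 3 genes of mitochondrial nitrogen metabolism. Cps1, the carbamoyl phosphate synthetase that starts the urea cycle, was at least 40.6-fold lower (adjusted p = 3.19e-08), and was detected on 3 of 8 knockout arrays. Nags, which makes the activator of that enzyme, was at least 5.65-fold lower (adjusted p = 6.11e-07), and Arg2, the mitochondrial arginase, at least 8.64-fold (adjusted p = 4.19e-06). Each of these 2 was detected on all 8 wildtype and on 2 knockout arrays. Ttr, the carrier of thyroxine and of retinol-binding protein, was not detected on any knockout array and was at least 6.87-fold lower there (adjusted p = 1.68e-08). Acer1, an alkaline ceramidase, was at least 9.89-fold lower and detected on 4 knockout arrays. Other genes in this set were the glutamate transporter gene Slc1a1 at -2.98, Rbp7, a retinol-binding protein, at -2.91, the adenosine deaminase gene Ada at -2.57 and Olfm4, a secreted crypt-base glycoprotein, at -2.31. The histone gene H2aj was at least 7.56-fold lower (adjusted p = 4.19e-13; detected on 1 knockout array) and the DNA sensor gene Aim2 at least 6.41-fold (detected on 3), and the ribonuclease gene Rnase2a (-2.48) completed the 12. Neighbours were counted among 365 of the genes changed at least 2-fold, those with a known chromosome place and outside the interferon list. Pairs whose symbols share their first 3 letters were left out. Of the pairs that remained, 89 were near neighbours, at most 5 tested genes apart, against 67.0 for genes drawn at random (permutation p = 0.00460). Hnf4a and Ada form such a pair. The labels do not settle whether the wildtype mice carry the loxP-flanked Hnf4a alleles. An inherited difference in the DNA beside Hnf4a is therefore not excluded as a source of the Ada difference. H2aj and Fgfr1op2 on chromosome 6, and Aim2, F11r, Nr1i3 and Fcer1g on chromosome 1, also stand in such pairs. So do Nags, Pyy, Ttr, Csrp1, Rnase2a, Ang4, Defa31, Cldn15, Anxa1, Neurog3, Trpm5, Nr5a2, Gcg, Saa3, Mmp3 and Ccl28. For all of these genes an inherited difference is not excluded either.

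Among the largest increases, the interferon-induced chemokine genes Cxcl10 and Cxcl9 rose 8.21-fold and 6.54-fold (log2 differences 3.04 ± 0.28 and 2.71 ± 0.32, SE; adjusted p = 1.12e-06 and 1.54e-05). Fgfr1op2 rose by 3.04, and the lectin gene Cd209b, detected on 3 wildtype arrays, at least 5.51-fold. Several other increases rested on wildtype values that were widely spread. Fcer1g, the Fc receptor gamma chain of myeloid and mast cells, was at least 17.0-fold higher (adjusted p = 0.00134), and was detected on 4 of 8 wildtype arrays and on all knockout arrays. Csrp1, a LIM-domain protein gene, differed by 3.09 with a wildtype SD of 2.44, and Retnlb, a goblet cell cytokine gene, by 2.80 with a wildtype SD of 1.65. The alpha-defensin genes Defcr-rs10, Defcr4 and Defa31, products of Paneth cells, differed by 4.49, 4.32 and 3.98 (SE 1.15, 1.39 and 1.36), and Defcr-rs12, detected on 2 wildtype and 6 knockout arrays, was at least 7.23-fold higher. The differences were larger on slide 2 than on slide 1 (for Defa31, 6.67 against 1.29). These genes are near-identical copies, and a probe for one can bind transcripts of another. Defa31 lost its call when any 1 of 11 arrays was left out (wildtype 1, 3, 5, 6 or 7, knockout 1, 4, 5, 6, 7 or 8; adjusted p between 0.0501 and 0.0689), and Defcr4 without wildtype array 1 (0.0512) or 6 (0.0527). Cyp2e1, a cytochrome P450, differed by 3.43 (SE 1.01, adjusted p = 0.0160). Adipocyte markers varied widely between arrays, with a list mean of 12.31 on knockout array 1 and 6.11 on knockout array 6, where Cyp2e1 read 14.13 and 5.39; with that mean as a covariate, a choice made after seeing the data, the difference in Cyp2e1 was 1.64 (adjusted p = 0.00594).

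For the gene lists, camera with the preset correlation called 12 of 35, 10 higher and 2 lower. Camera called none with an estimated correlation, where the lowest adjusted p was 0.162 and 4 lists had an unadjusted p under 0.05, while fry called 15, and 24 of 100 splits of the arrays gave 12 or more called lists. The exact permutation test of list means per array, which keeps the correlation between members, passed 15 lists, 10 higher and 5 lower. It compares the genotypes for each list and does not set the list against other genes.

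**Figure D2:**
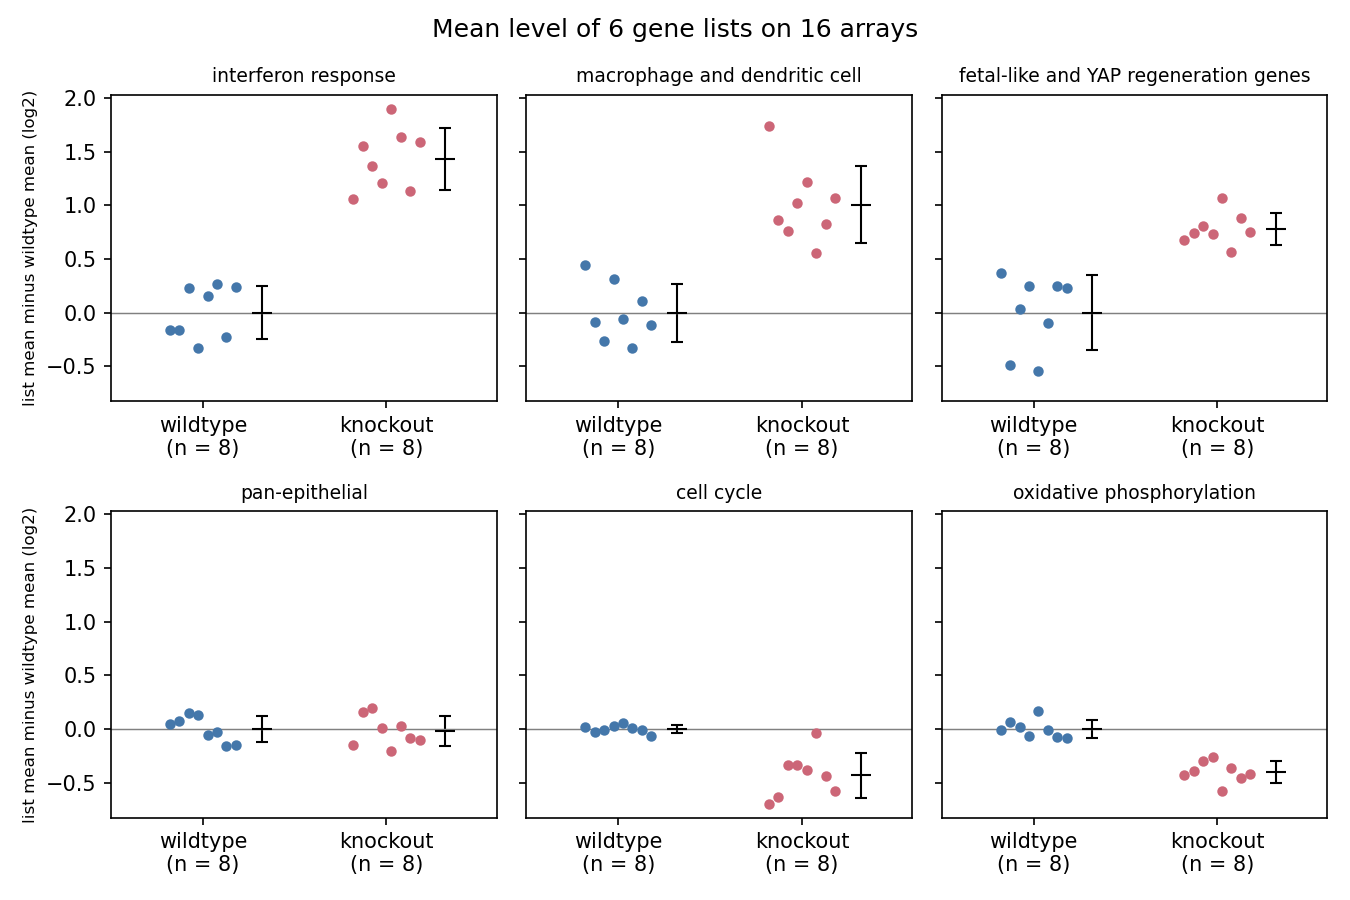
Mean log2 level of the members of 6 gene lists on each array, relative to the wildtype mean (vertical axis), for 8 wildtype (blue) and 8 knockout (red) arrays; black bars give the group mean and SD. The interferon, macrophage and fetal-like lists lie higher and the cell cycle and oxidative phosphorylation lists lower in knockout tissue, while the pan-epithelial means overlap.

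Of the lists that passed, the interferon response list rose most. Of 25 tested members 23 rose and none fell, also 23 when adjusted over the list alone, with a median log2 difference of 1.40. Besides the chemokines, Oas2 rose by 2.60 and Ifit3 by 2.54, both antiviral effectors. The list mean went from 8.46 ± 0.24 to 9.89 ± 0.29 (SD, n = 8 each; exact permutation adjusted p = 0.00109; camera adjusted p = 8.76e-20, with slide as a block 1.64e-19). The adjusted p was 0.162 with an estimated correlation. The median was 1.39 on slide 1 and 1.27 on slide 2. Macrophage markers rose too, and the interferon mean exceeded theirs by 0.42 more in knockout tissue (exact permutation p = 0.116).

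Markers of macrophages and dendritic cells rose as well, 12 of 14 both over all genes and adjusted over the list alone, with a median of 0.73. Beside Fcer1g, the mannose receptor gene Mrc1 rose by 1.25, the lysozyme gene Lyz2 by 1.16 and Cd68 by 1.06. The list mean was 1.01 higher in knockout tissue (SD 0.27 in wildtype and 0.36 in knockout tissue, n = 8 each; exact permutation adjusted p = 0.00109; camera adjusted p = 3.42e-07, with slide as a block 5.10e-07), with an adjusted p of 0.418 with an estimated correlation. Slide medians were 0.88 and 0.58. Fcer1g differed by 4.44 with a wildtype SD of 2.78, so it raised the difference in the list mean. Camera's call was kept with genes of a wildtype SD above 1 left out, Fcer1g among them. This call, at the preset correlation, is not a test of the list mean per array. Endothelial markers rose too, 7 of 12 (7 adjusted over the list alone), with a median of 0.57 and Pecam1, an endothelial adhesion molecule, at 1.07 (exact permutation adjusted p = 0.00121; camera adjusted p = 0.000160, with slide as a block 0.000256; adjusted p = 0.418 with an estimated correlation). Slide medians were 0.68 and 0.45. Fibroblast and matrix markers had 5 of 11 higher (6 adjusted over the list alone), with Thy1 at 0.81 and Lum at 0.86. Lum lost its call when any 1 of 9 arrays was left out (wildtype 1, 2, 3, 5 or 6, knockout 1, 5, 7 or 8; adjusted p between 0.0522 and 0.0737). Camera called this list (adjusted p = 0.0136, with slide as a block 0.0162; 0.623 as the adjusted p with an estimated correlation), while the exact permutation test did not (adjusted p = 0.0527), nor did camera on slide 2 alone (adjusted p = 0.125, slide medians 0.55 and 0.31). With the adipocyte mean as a covariate, chosen after seeing the data, the fibroblast median was 0.28 and Lum differed by 0.42, both no longer past the threshold (adjusted p = 0.158 and 0.160). With the macrophage mean as a covariate, which goes with genotype, both changed sign. The fibroblast median was then -0.47 (camera adjusted p = 0.112) and Lum differed by -0.64 (limma adjusted p = 0.373).

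The list of fetal-like and YAP target genes, which mark regenerating intestinal epithelium, rose for 13 of 22 members with none lower (14 adjusted over the list alone). Its median was 0.66. Among them the annexin gene Anxa1 rose by 1.43 (SE 0.29, adjusted p = 0.00142) and the mesothelin gene Msln by 1.43 (SE 0.28, adjusted p = 0.00102). Each of these 2 genes lost its call in 2 of 38 alternatives (highest limma adjusted p 0.429 and 0.509). Their lowest differences over the alternatives were 0.75 and 0.58. The mean went from 9.76 ± 0.35 to 10.54 ± 0.15 (SD, n = 8 each; exact permutation adjusted p = 0.00109; camera adjusted p = 9.30e-08, with slide as a block 1.39e-07), with an adjusted p of 0.418 with an estimated correlation. Slide medians were 0.58 and 0.83. Whole tissue does not say which cells carry these transcripts, and the interferon, macrophage and endothelial lists rose on the same arrays. A change of state in the epithelium was therefore not tested by this list. With the macrophage mean as a covariate the calls of the endothelial and TGF-beta lists were lost (adjusted p = 0.798 for both). TGF-beta and matrix remodelling genes had 8 of 20 higher and none lower (11 adjusted over the list alone), among them Lox at 1.22, the protease gene Mmp3 at 1.16 and Tgfb1 at 0.95 (exact permutation adjusted p = 0.00494; camera adjusted p = 5.80e-05, with slide as a block 6.87e-05; adjusted p = 0.418 with an estimated correlation, slide medians 0.60 and 0.56). The antimicrobial and acute inflammation list rose on balance, with 10 of 17 higher and 2 lower (10 and 3 adjusted over the list alone). The neutrophil chemoattractant gene Cxcl1 rose by 2.46, Lcn2 by 1.22 and Saa3 3.03-fold, while Il18 fell by 0.98 (exact permutation adjusted p = 0.00499; camera adjusted p = 0.0136, with slide as a block 0.0157; adjusted p = 0.418 with an estimated correlation, slide medians 0.45 and 0.74).

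Cell cycle genes fell together. Of 28 tested, 20 were lower and none higher (21 adjusted over the list alone), with a median of -0.45. Rrm2, a subunit of ribonucleotide reductase, fell by 0.82, Birc5 by 0.73, Cks2 by 0.69 and the mitotic kinase gene Aurka by 0.68. The mean went from 10.01 ± 0.04 to 9.58 ± 0.21 (SD, n = 8 each; exact permutation adjusted p = 0.00121; camera adjusted p = 1.83e-07, with slide as a block 1.66e-07), with an adjusted p of 0.418 with an estimated correlation. Slide medians were -0.48 and -0.36. With the macrophage mean as a covariate, a choice made after seeing the data, the median was -0.21 and camera's call was lost (adjusted p = 0.112). Oxidative phosphorylation genes fell for 18 of 21 members and rose for none (18 adjusted over the list alone), with a median of -0.39. Sdhc, a subunit of succinate dehydrogenase, fell by 0.88, Atp5o by 0.70 and Cyc1 by 0.62; another Sdhc probe pointed the other way. The list mean passed (exact permutation adjusted p = 0.00109; camera adjusted p = 3.53e-08, with slide as a block 3.58e-08; adjusted p = 0.418 with an estimated correlation, slide medians -0.34 and -0.41).

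Pan-epithelial markers such as keratins and cadherins had 1 of 11 past the threshold (0 adjusted over the list alone), Krt20 at 0.35, and the call of Krt20 was lost with 75th percentile scaling (adjusted p = 0.286). Their list mean was 12.45 ± 0.12 in wildtype and 12.43 ± 0.14 in knockout tissue (SD, n = 8 each; exact permutation adjusted p = 0.822), and slide medians were -0.04 and -0.000186. Smooth muscle markers had 0 of 9 past the threshold by limma, and 0 at an unadjusted p under 0.05, with Flna at 0.41 (adjusted p = 0.214, and 0.0281 without knockout array 6) and a list mean of 10.91 ± 0.53 against 11.03 ± 0.81. Slide medians were 0.33 and -0.11.

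Of the secretory lineages, the Paneth, goblet and enteroendocrine lists rose in list mean and the tuft cell list did not pass. Paneth cell markers had 6 of 13 higher and 1 lower (the same numbers adjusted over the list alone), with Ang4, a bactericidal ribonuclease, at 1.19 and the phospholipase gene Pla2g2a at -1.71. The list passed both tests (exact permutation adjusted p = 0.00879; camera adjusted p = 0.0115, with slide as a block 0.0123, slide medians 0.59 and 0.52; adjusted p = 0.482 with an estimated correlation), and camera's call was lost with 75th percentile scaling (adjusted p = 0.0874) and median scaling (0.0819). The mean difference of the Paneth list was 0.93, against a median of 0.76. Defcr4 and Defa31, at 4.32 and 3.98, weighed on that mean, and as near-identical copies they are not separate evidence. Camera's call was kept with genes of a wildtype SD above 1 left out, Defcr4 and Defa31 among them. That call is at the preset correlation and does not test the list mean per array. Goblet cell markers had 4 of 11 higher (4 adjusted over the list alone), with Retnlb at 2.80, Ccl6 at 1.32, Sytl2 at 0.66 and the mucus protein gene Clca1 at 0.60. The other Sytl2 probe pointed the other way, and Clca1 lost its call with 75th percentile scaling (adjusted p = 0.132). The median was 0.13 (exact permutation adjusted p = 0.00121; camera adjusted p = 0.0391, with slide as a block 0.0349, slide medians 0.17 and 0.13; adjusted p = 0.418 with an estimated correlation). Camera's call was lost with 75th percentile scaling, where the median was 0.0135 (adjusted p = 0.142), with median scaling, where it was 0.00443 (adjusted p = 0.140), with array weights (0.0722), on slide 2 alone (0.0623) and without wildtype array 1 (adjusted p = 0.0511), 5 (0.0501) or 7 (0.0556) or knockout array 3 (0.0904) or 7 (0.0589). The goblet call was also lost with genes of a wildtype SD above 1 left out, Retnlb (wildtype SD 1.65) among them. The mean difference of the goblet list was 0.52, above its median, since Retnlb and Ccl6 weighed on it. Enteroendocrine markers had 10 of 17 higher and 3 lower, the same adjusted over the list alone. The hormone genes Pyy, Ghrl, Cck and Gcg rose by 1.89, 1.85, 1.56 and 1.35. Neurog3, 1 of the 3 lower members, fell by 1.23. The mean difference of the list was 0.47, against a median of 0.72. The list mean rose (exact permutation adjusted p = 0.00121; camera adjusted p = 0.0406, slide medians 0.93 and 0.51; adjusted p = 0.418 with an estimated correlation), but with slide as a block camera gave an adjusted p of 0.0546. Its call was also lost without wildtype array 1 (0.0583) or 7 (0.0565) or knockout array 3 (0.0729), 6 (0.0507) or 8 (0.0517), with array weights (0.0605), with camera on ranks (0.105) and on slide 2 alone (0.121). With no detection filter the median was 0.18, against 0.72, and the call was lost (0.0514). Of 7 tuft cell markers, Avil (1.80) and Ptgs1 (0.50) were higher and Plcg2 (-0.40) and Trpm5 (at least 1.89-fold, detected on 1 knockout array) lower, the same numbers adjusted over the list alone, and the list mean did not pass (exact permutation adjusted p = 0.151). Ptgs1 lost its call without wildtype array 2 (0.0506) or 3 (0.0503) or knockout array 2 (0.0501).

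Genes for Notch signalling and secretory specification were lower in list mean on all 8 knockout arrays than the wildtype median (exact permutation adjusted p = 0.00109; camera adjusted p = 0.138, slide medians -0.35 and -0.15). Of 11 members 5 were lower and 1 higher, the same adjusted over the list alone: Neurog3, the enteroendocrine progenitor factor, fell by 1.23, Hes6 by 0.92 and Nrarp by 0.54, and Foxa1 rose by 0.50. Intestinal transcription factors had 6 of 20 lower and 1 higher (7 and 3 adjusted over the list alone). The vitamin D receptor gene Vdr fell by 1.31 and the xenobiotic receptor gene Nr1i2 by 0.89, and Nr1i3 and Nr5a2, detected on 4 and 3 knockout arrays, were at least 1.97-fold and 1.91-fold lower (exact permutation adjusted p = 0.0120; camera adjusted p = 0.104, slide medians -0.29 and -0.23). Stem cell markers passed the permutation test of the mean (exact permutation adjusted p = 0.0181; camera adjusted p = 0.327, slide medians -0.11 and -0.10), with 2 of 12 lower, Olfm4 and the Wnt target Axin2, which fell by 0.41 (2 adjusted over the list alone). The enteric neuron and glia list passed the same test with 1 of 5 members higher (2 adjusted over the list alone), the receptor gene Ret at 2.05 (exact permutation adjusted p = 0.00163; camera adjusted p = 0.104, slide medians 0.57 and 0.51). Single genes weighed on both means. The stem cell list had a mean difference of -0.24 and a median of -0.10, with Olfm4 at -2.31. The enteric list had a mean difference of 0.66, Ret included, and a median of 0.54. Neither list was tested without that gene.

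Lists for the work of the mature absorptive cell passed neither test over all arrays. Brush border genes had 3 of 21 lower (1 adjusted over the list alone; exact permutation adjusted p = 0.425), with the peptidase gene Xpnpep2 at -1.34, the amino acid transporter gene Slc6a19 at -1.21 and Ush1c at -0.28. Lipid absorption genes had 1 of 18 higher, Apoc3 at 1.28, and 2 lower, the acyltransferase genes Mogat2 at -1.16 and Dgat1 at -0.89 (0 and 2 adjusted over the list alone; exact permutation adjusted p = 0.563). Drug metabolism and bile acid genes had 5 of 21 lower (5 adjusted over the list alone; exact permutation adjusted p = 0.0723), including Cyp2d26 at -1.82, the transporter gene Abcc2 at -1.61, Ces2e at -1.19 and Gsta1 at -1.13. Fatty acid oxidation had 5 of 22 lower and 1 higher (9 and 1 adjusted over the list alone; camera adjusted p = 0.0578), with Hadh at -0.73, Etfb at -0.46, Cpt2 at -0.39 and Decr1 at -0.39. Camera called this list as lower in 17 of 38 alternatives, among them 75th percentile scaling (adjusted p = 0.0372), median scaling (0.0380), no detection filter (0.0110), every probe tested (0.0132), the mean of a gene's probes (0.0372) and array weights (0.0485), and without wildtype array 3 (0.0382), 4 (0.0464), 6 (0.0487) or 8 (0.0331) or knockout array 1 (0.0163), 2 (0.0490) or 4 (0.0474). On slide 2 alone camera called the brush border (0.0156), lipid (0.0457), fatty acid (0.00244) and drug metabolism (0.0179) lists as lower, and on slide 1 alone the brush border median was -0.01. Leaving out 1 array ended the call of Slc6a19 (any of 9 arrays, adjusted p up to 0.0901), Ush1c (10 arrays, up to 0.0924), Apoc3 (10 arrays, up to 0.0800), Ckmt1 (10 arrays, up to 0.0867), Decr1 (8 arrays, up to 0.0651) and Cpt2 (wildtype 2 or knockout 2 or 8, up to 0.0595). Proximal small intestine genes had 1 of 8 lower, Ckmt1 at -0.29 (0 adjusted over the list alone), and distal ones 1 of 9 higher, Pyy (1 adjusted over the list alone); the distal list's median was -0.21 and its mean 0.09, of opposite sign.

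The other lists did not pass. Junction and adhesion genes went both ways, with 3 of 18 higher and 2 lower, the same adjusted over the list alone: Cldn15, a claudin of the small intestine, fell by 1.74 (adjusted p = 5.32e-07), and F11r rose by 1.40, Cldn4 by 0.92 and Cldn23 by 0.45. Targets of p53 had 3 of 24 higher (3 adjusted over the list alone), Phlda3 at 0.71, Fas at 0.55 and Cdkn1a at 0.27, which lost its call with 75th percentile scaling (adjusted p = 0.595). Glycolysis and hypoxia genes had 5 of 16 lower and 1 higher, the same adjusted over the list alone, with Car9 at -1.04, Pdk1 at -0.59, Pfkp at -0.50 and Hk1 at 0.88; Pfkp lost its call without wildtype array 1 (0.0505) or 5 (0.0519) or knockout array 7 (0.0524). Cholesterol synthesis genes had 3 of 19 lower (1 adjusted over the list alone), among them Nsdhl at -0.43 and Stard4 at -0.38. Nsdhl lost its call without any 1 of 11 arrays (adjusted p up to 0.0797) and Stard4 without any 1 of 7 (up to 0.0688). Wnt targets had 2 of 13 lower, Sp5 at -0.97 and Axin2, and Dkk3 higher at 0.63 (2 and 1 adjusted over the list alone). The unfolded protein list had 1 of 18 higher, Dnajb9 at 0.41 (0 adjusted over the list alone), which lost its call with 75th percentile scaling (adjusted p = 0.0958). Lymphocyte lists had 1 of 7 lower for T and NK cells, Cd3e at -0.58, and 1 of 5 for B and plasma cells, Tnfrsf17, at least 1.33-fold and detected on 2 knockout arrays (1 each adjusted over the list alone). The B and plasma cell list had a median of -0.01 on slide 1 and of -0.77 on slide 2, where camera called it (adjusted p = 0.0408). Of 5 neutrophil markers none passed by limma, and none at an unadjusted p under 0.05, with Csf3r at 0.28 (adjusted p = 0.182). Of 6 adipocyte markers Cidec passed at 1.04 (1 adjusted over the list alone), with a list mean of 8.08 ± 1.47 against 9.49 ± 1.82 (SD, n = 8 each; exact permutation adjusted p = 0.151). Camera called the adipocyte list without knockout array 6 (adjusted p = 0.0331), and Cidec lost its call without wildtype array 1 (0.0556), 6 (0.0565) or 7 (0.0550). With 3 tested members, exocrine pancreas was not tested as a list (Clps at 0.59, adjusted p = 0.124), and no erythroid member passed the detection filter.

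**Figure D3:**
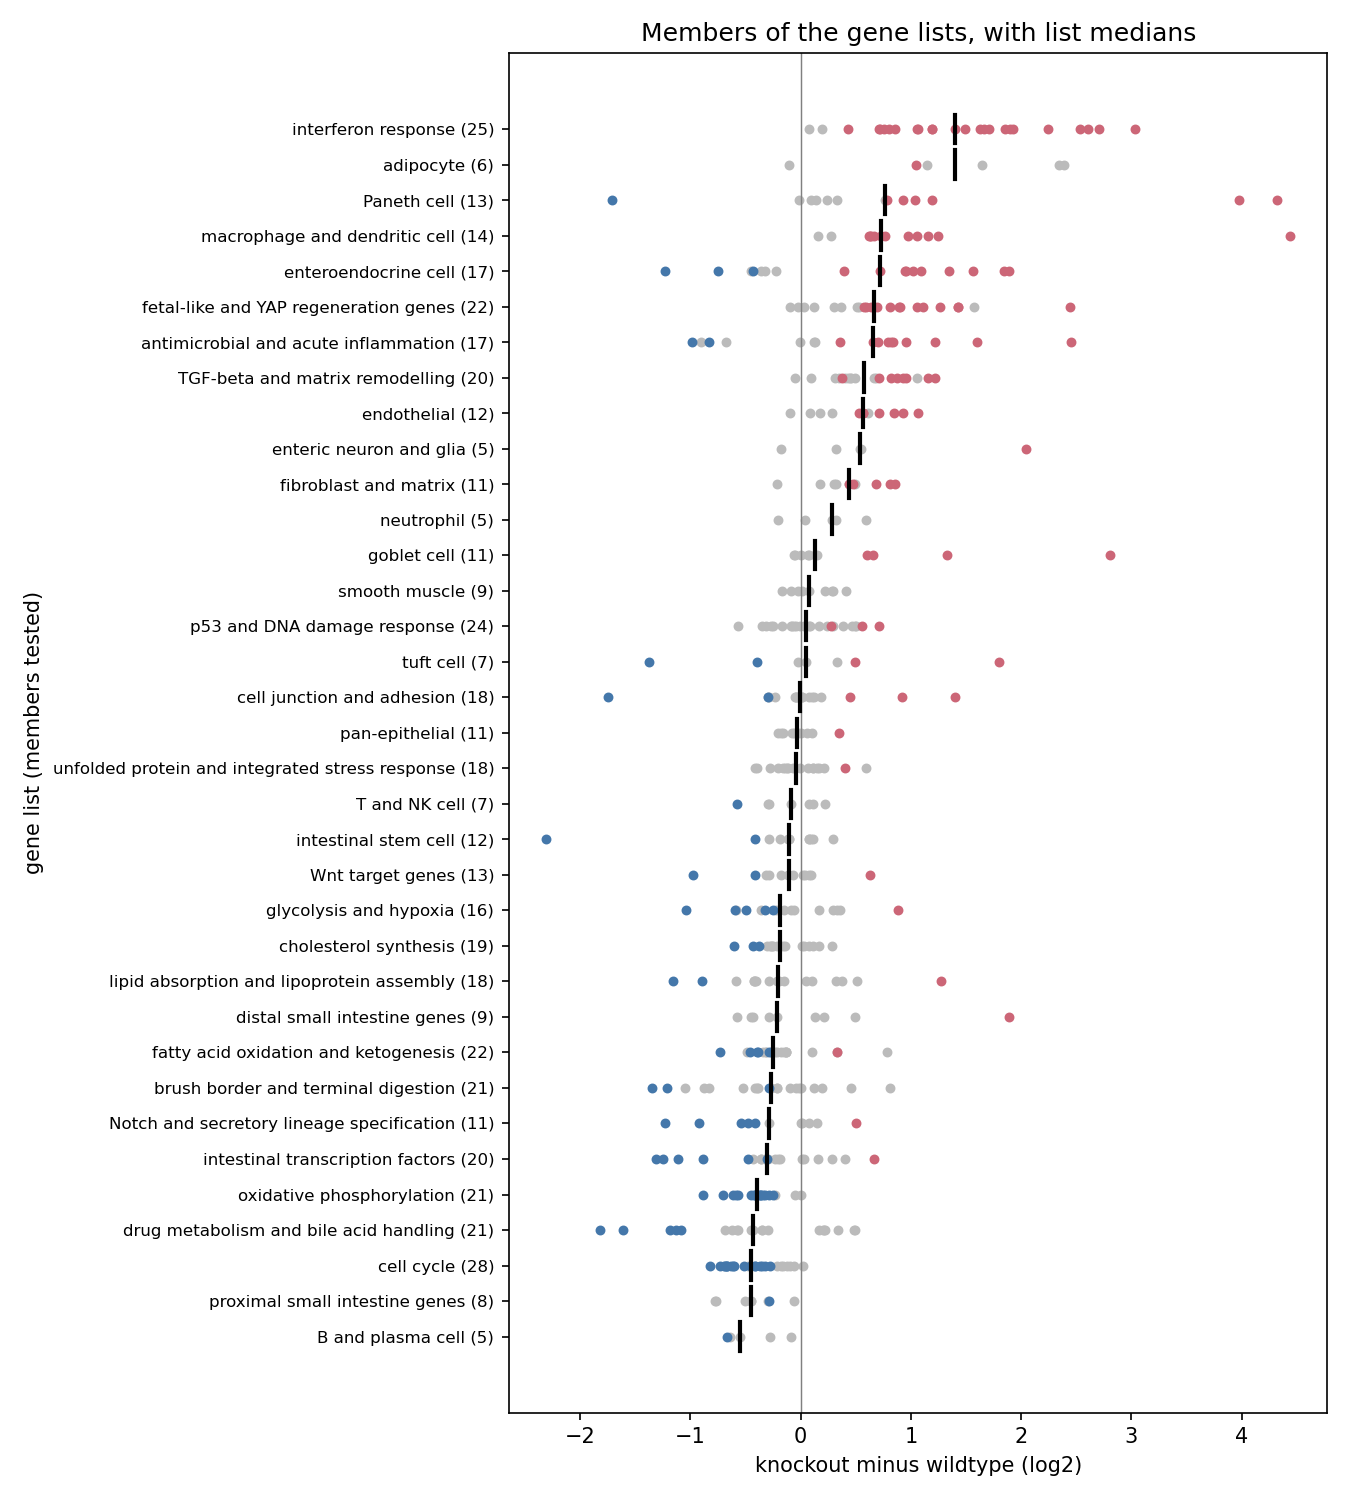
Knockout minus wildtype log2 difference (horizontal axis) of each tested member of the 35 gene lists (vertical axis, number of members in brackets). Red points passed the threshold as higher, blue as lower, grey did not pass; black bars are list medians, from 1.40 for the interferon list to -0.55 for B and plasma cells.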

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

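The tests of neighbouring genes, of Cyp2e1, of the interferon list and of the cell cycle list against pan-epithelial markers were chosen after the results were seen. The splits of the arrays, the fat adjustment of the other genes and the adjustment of the cell cycle list for muscle and fat were set before their values were computed.

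Among 310 groups of 8 values, 17 held an array far from the others (a gap to its nearest neighbour above Dixon's critical value for 8 at 95%), against 15.5 expected by chance at 1 in 20. Knockout array 2 was lowest for Defcr4 (6.96), Defa31 (6.65) and the Paneth cell list mean (12.54). Knockout array 6 was lowest for Flna (8.62), Pdgfra (9.90), Dkk3 (9.95) and the smooth muscle list mean (9.10). Knockout array 1 was highest for Cdh5 (7.37) and Cidec (12.47) and lowest for Avil (9.21) and the junction list mean (9.88). Knockout array 8 was highest for H2aj (5.92). Wildtype array 2 was highest for Defcr-rs12 (8.68) and lowest for Cxcl1 (5.95). Wildtype array 1 was lowest for Nr5a2 (5.71), wildtype array 8 lowest for Pdk1 (8.75), and wildtype array 5 highest for the mean of proximal small intestine genes (9.97).

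Chance is argued against for the number of genes, as far as 100 splits can show. The real grouping gave 3115 genes, the highest of the other splits 376, and 1 of 100 splits gave as many, the real one. A split by slide gave 152. For the number of called lists chance cannot be excluded: the real grouping gave 12, the highest other split 17, and 24 of 100 splits gave at least 12. The median of the other splits was 9 lists with a median of 0 genes, so the preset correlation of 0.01 called lists in groupings that hold no called genes. Many of these splits had 5 or more knockout arrays on 1 side, so part of the genotype difference can enter them. The 24 of 100 is thus not a rate in the absence of any difference.

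Genes changed at least 2-fold are the first pattern. Differing amounts of fat could not account for most: with the adipocyte mean as a covariate 94.3% of 403 other genes stayed past the threshold. For Cyp2e1 the difference dropped from 3.43 to 1.64 (adjusted p = 0.00594), so part of it may go with fat. Inherited variants remain a candidate explanation for some genes. Among 365 genes of this set with a known place and outside the interferon list, 89 pairs were neighbours, against 67.0 by chance (permutation p = 0.00460). Pairs with a shared symbol prefix were left out of that count, and 40 of the 89 had opposite signs. Clusters of jointly regulated genes would raise the count too, and the loss of HNF4A stays open for all of these genes.

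The rise of the interferon list is the second. With the mean of the macrophage and dendritic cell markers as a covariate the interferon mean differed by 1.84 (SE 0.24), against 1.43 (SE 0.13) without. Within genotypes the 2 means correlated at -0.486, so this fit could only enlarge the difference. It therefore cannot decide whether more macrophages and dendritic cells are the whole cause. Of the 23 genes that rose 18 (78.3%) stayed past the threshold in that fit, short of the 80% first asked for, a criterion replaced by the difference in the mean after that share was seen. Macrophages as part of the cause cannot be told apart from a rise within cells: the interferon mean rose by 0.42 more than the macrophage mean (exact permutation p = 0.116), and 74.2% of the variance of the macrophage mean lay between genotypes. The macrophage mean includes Fcer1g, which differed by 4.44 with a wildtype SD of 2.78 and so narrowed that gap. Neither this comparison nor the covariate fit was repeated without Fcer1g. A response of the knockout epithelium stays open and was not tested, because whole tissue does not say which cells carry the transcripts.

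The fall of the cell cycle list is the third. A lower share of epithelium is argued against, because the list fell by 0.41 relative to the pan-epithelial mean (exact permutation p = 0.000932). Varying muscle and fat are argued against as well: with both means as covariates the median was -0.41, against -0.45 without. With the macrophage mean as a covariate the cell cycle mean differed by -0.19 (SE 0.13), against -0.43 (SE 0.08) without, and camera's call was lost (adjusted p = 0.112), because the difference shrank and its SE grew in a fit whose covariate goes with genotype, so a change in cell composition stays open. A smaller share of dividing cells within the epithelium and lower expression per dividing cell remain open as untested.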

How the results depend on the processing

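The alternatives were set before the data were examined, except 4 chosen after seeing the data: the adipocyte and macrophage covariates, leaving out knockout arrays 1 and 6 together (3164 genes), and leaving out genes with a wildtype SD above 1 (3095 genes). Hnf4a stayed lower under all 38 alternatives, between -1.89 and -1.53. Leaving out 1 array at a time gave 2636 to 3361 genes (1116 to 1537 higher, 1520 to 1824 lower), 10 to 13 lists by camera and 15 to 19 by permutation of list means. The median of all genes was -0.05 with median scaling, against -0.02, and 37.1% of called genes were higher there, against 44.1%. Over 32 alternatives set beforehand that kept at least 15 arrays, the threshold and camera on the moderated statistics with the preset correlation, 97 of 119 named genes and 25 of 35 lists never crossed the threshold, and none changed sign while called. With the 3 other list tests included (an estimated correlation, fry and camera on ranks), 14 of 35 lists never crossed it. Median scaling and 75th percentile scaling each ended the calls of Krt20, Pdgfra, Clca1, Apoc3, Cldn23, Nsdhl, Cdkn1a and Dnajb9, and leaving out the detection filter those of Apoc3, Nsdhl, Defa31, Lum, Cidec, Slc6a19, Ush1c and Ckmt1. Slide 1 alone gave 758 genes (362 higher, 396 lower) and slide 2 alone 1335 (605 and 730), and fewer arrays are part of these lower gene counts. Slide 2 alone also gave 7 lower lists, against 2 over all arrays, and the cause was not tested. List means passed by exact permutation for 0 lists on each slide (10 on each at an unadjusted p under 0.05), because 4 against 4 cannot give a p under 0.0286 and 20 lists would have to reach it. An adjusted p under 0.01 left 1741 genes (741 and 1000), and a further 2-fold limit at 0.05 left 405 (256 and 149). Lower lists numbered 5 with no detection filter, 4 with every probe tested and 5 with fry, against 2; the cause was not tested. Lists called only in an alternative included the transcription factor (adjusted p = 0.0363) and proximal (0.0417) lists with no detection filter, enteric neurons with a stricter one (0.0403), and cholesterol synthesis and p53 (0.0498 each) with every probe tested. Fry added the enteric neuron (0.00366), stem cell (0.0415), transcription factor (0.0172) and Notch (0.00125) lists and lost the fibroblast list (0.0570), and ranks added fatty acid oxidation (0.0262). With an estimated correlation camera called 0 lists, 0 higher and 0 lower (4 at an unadjusted p under 0.05).

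With the macrophage mean as a covariate 509 genes were called (273 higher, 236 lower), 374 of them among the 3115, 4 lists were lower and 0 list means passed by exact permutation (0 also at an unadjusted p under 0.05); 71 named genes lost their call. That mean shares 74.2% of its variance with genotype, so the fit removes much of the genotype difference itself. For the permutation test the covariate was taken out of each list mean before genotypes were compared, so its 0 passing lists say little. The interferon difference of 1.84 given above came from a fit of covariate and genotype together. Medians changed sign for 13 lists, 8 of which passed in neither fit (lipid absorption at 0.41 and cholesterol synthesis at 0.0840 among them). The others were the smooth muscle (-1.14), fibroblast (-0.47), adipocyte (-2.82), brush border (0.65) and junction (0.32) lists, with camera adjusted p of 0.00761, 0.112, 0.0326, 0.00761 and 0.00525. Camera's call was lost for the endothelial (0.15, adjusted p = 0.798), TGF-beta (0.30, 0.798), cell cycle (-0.21, 0.112) and Paneth cell (0.60, 0.133) lists. It was kept for the interferon list (1.65), as in all 38 alternatives with the preset correlation (adjusted p at most 5.05e-16), and Cxcl10, Cxcl9, Oas2 and Ifit3 stayed past the threshold. The difference changed sign for Flna (-0.35), which passed in neither fit, and for Cyp2e1 (-2.02), Lum (-0.64), Lyz2 (-0.50), Cd68 (-0.65), Cidec (-0.42), Dkk3 (-0.33), Slc6a19 (0.12), Ush1c (0.16), Ckmt1 (0.13), Nsdhl (0.0874), Stard4 (0.0840) and Pfkp (0.11), none of them past the threshold with the covariate.

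The replicate numbers were not taken to pair the mice, since the labels name no shared litter or day and not every pair deviated together: deviations of same-numbered arrays correlated between -0.23 and 0.39, 6 of 8 pairs over 0.1, and 2 of 8 wildtype arrays correlated best with their own number. With the replicate block 3460 genes were called, and the enteroendocrine list (adjusted p = 0.0607), Defcr4 (0.0542), Defa31 (0.0770), Ush1c (0.0501) and Ckmt1 (0.0585) were not past the threshold. The variance models and array weights do not enter the permutation test of list means and were not run for it. Dim probes limit what can be seen, since the offset of 16 pulls their differences toward 0.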

Other observations

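Families of gene symbols were examined after the data were seen. Fisher's exact test was run on 144 families of at least 8 tested members in both directions, adjusted over all 288 tests. Genes of a family are not independent, so the mean per array was also compared by exact permutation for the 14 families that passed. These families were picked from the same arrays, so small permutation p-values were to be expected and are not separate evidence. Mitochondrial ribosomal protein genes (Mrpl and Mrps) stood out: 58 of 70 were lower and none higher in knockout tissue (adjusted p = 6.53e-31), with a median of -0.41. Their mean went from 10.74 ± 0.08 to 10.31 ± 0.10 (SD, n = 8 each; exact permutation p = 0.000155, the smallest possible), and Mrpl15 fell by 1.02. Genes of respiratory complex I and its assembly (Nduf) had 28 of 39 lower (adjusted p = 1.05e-11), some of them also members of the oxidative phosphorylation list. Import subunits of the inner mitochondrial membrane (Timm) had 7 of 12 lower and exosome subunits (Exosc) 7 of 10 (adjusted p = 0.0341 and 0.0103). The medians of these families kept their sign with no background correction, 75th percentile scaling, median scaling and the deposited series table.

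On the other side, chemokine genes of the Ccl family had 12 of 17 higher (adjusted p = 1.12e-05), with Ccl2 at 1.63 and Ccl7 at 1.71, while Ccl28, a chemokine of mucosal epithelium, fell by 2.08. Major histocompatibility genes (H2-) had 13 of 22 higher and none lower (adjusted p = 5.33e-05), with H2-T23 at 0.99 and H2-DMa, which works in class II loading, at 0.64. Genes of the Ly group had 10 of 14 higher (adjusted p = 6.92e-05), with Ly6c1 at 1.61. These medians kept their sign in the same 4 alternatives.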
